A study of Mus musculus with 4 samples.

How the data were processed

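Gene expression was measured in mesothelial and submesothelial cells taken surgically from the livers of C57BL/6 mouse embryos at embryonic day 17.5, per the labels. Mesothelium is the cell sheet that covers the organ surface, and the submesothelial cells lie directly beneath it. The cells came from embryos without p57, the product of Cdkn1c, or from wild-type embryos, written p57-/- and p57+/+. There were 4 samples, 2 of each genotype. The sample titles assign 1 sample of each genotype to experiment 1 and 1 of each to experiment 2. These numbers were used as replicate numbers, and what an experiment shared is not stated. Per the labels' protocols, RNA was extracted with a column kit, and biotin-labelled cRNA was made from 250 ng of total RNA with a kit that primes from the 3' end. Each sample was read on 1 single-colour Affymetrix array with 45101 probe sets, of which 64 were controls. The labels do not say whether samples were single embryos, pools or litters, so p-values measure only the spread between these samples, which may be partly technical. Between the p57+/+ samples it includes a difference of sex, as the sex-linked genes given below show.

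The authors deposited, for each array, the MAS5 signal of each probe set on a linear scale, as the file headers and the submitters' processing notes name it. They also deposited a detection p-value per probe set with a call of Present, Marginal or Absent, per the file headers. The MAS5 version, scanner settings and background steps are not given in the sources used here. The mean of the deposited signals after trimming 2% at each end was 500.003 on all 4 arrays, so each array had been scaled to the same target. The deposited value table of the series held the same signal values, with a largest relative difference of 0.0005%. Its scale was linear and uncentred. Scaling to a common mean fixes the average of each array. It hides a change in total RNA, and it leaves the signals of dim probe sets noisy on the log2 scale.

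Signals were log2 transformed without further normalization and without a pseudocount. Controls were left out, and a probe set was tested if it was called Present on at least 2 of the 4 arrays, whatever the genotype. This left 22800 probe sets for 11656 genes. The genotypes were compared with limma 3.58.1 in R 4.3.3 (lmFit, then eBayes with a variance trend on mean signal), with no block, two-sided, and Benjamini-Hochberg adjustment over the probe sets tested. The threshold was an adjusted p of 0.05. A log2 change is p57-/- minus p57+/+. Where a probe set was Absent on both arrays of a genotype, the fold is given as a bound: the mean log2 signal of the brighter genotype was set against the higher of the array's lowest Present signal and the probe set's own signal. The number of arrays limits the precision.

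Beside the test, tested probe sets at least 2-fold changed the same way in both experiments were counted, each p57-/- array being set against the p57+/+ array of the same number. The count of probe sets changed in opposite ways is the level that needs no shared effect.

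Gene symbols came from the platform annotation supplied for the value table. Of the probe sets that are not controls, 34945 had 1 symbol, 932 had several and 9160 had none. Of those with 1 symbol, 34754 had their gene in the RefSeq table of the GRCm38.p6 assembly, and 0 of these symbols differed. That table was used only for names and gene order. Probe sets with several or no symbols were tested but not named.

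Before the data were examined, 31 gene lists were fixed for cell types of the liver surface and its neighbours, cell cycle, imprinted genes, signalling, matrix and stress. A list was tested if at least 5 of its genes were tested, which held for 27. The 4 others were bile duct epithelium, skeletal muscle, pancreas, gut and adrenal neighbours, and sex-linked genes. Lists were compared with all other genes by limma's camera with a preset inter-gene correlation of 0.01, using the probe set of highest mean log2 signal for each gene. Adjustment ran over the lists, with a threshold of 0.05. The camera test with an estimated correlation and the directional fry test were alternatives. With an estimated correlation, camera rests on the few residual degrees of freedom that 4 arrays leave, so it can call little. The fry test asks a different question, whether a list's genes changed in a shared direction, without comparing them with other genes. Its mixed form allows changes either way and was not counted among the alternatives. Members were also adjusted over the list alone. A list's median and mean are over the log2 changes of its tested genes.

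The genes named were chosen by a rule fixed before the data were examined. It took Cdkn1c, then up to 12 genes per direction past the threshold and changed the same way in both experiments. Where fewer than 12 passed, it was filled with the genes of largest log2 change among those at least 2-fold changed that way in both experiments. It also took the 2 members of largest change in each tested list, and up to 3 brightest members of each cell type list as levels. Members past the threshold when adjusted over the list alone, and other genes so marked, were named after their values were seen.

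The functions were tested on simulated data, with 20 simulations of 4 arrays over the 22800 probe sets and 200 changed probe sets each. Variances were drawn from the fitted prior. Of the changed probe sets, 43.5% were recovered at 2-fold, 81.9% at 4-fold, 90.8% at 8-fold and 93.5% at 16-fold, and 4.82% of calls were false. With each probe set's own variance estimate in place of the prior, 64.3% were recovered at 2-fold and 8.78% of calls were false. For lists of 20 independent genes, camera at the preset correlation called 100% of those shifted by 0.4 on the log2 scale and 0.75% of unshifted ones. The simulated probe sets and genes varied independently, which the measured ones need not. The changed probe sets were spread evenly over the 4 sizes. With fewer or smaller true changes the adjusted threshold is harder to reach. The recovered shares are therefore not rates for the measured arrays.

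Alternatives changed the normalization, the pseudocount (16 or 64), the filter on dim probe sets, the variance model, the threshold, the source of the values, the replicate block, the set test and the probe set per gene, or left out 1 array at a time. Figures were drawn with matplotlib 3.10.9 in Python 3.11.15.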

Results

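The comparison asks how gene expression in the surface cell layers of the fetal liver differs between embryos with and without p57. Each array had 48.5% to 50.1% of its probe sets called Present. The median signal lay between 76.4 and 83.0, and the lowest Present signal between 12.4 and 15.4. Across probe sets, the log2 signals of pairs of arrays had Pearson correlations from 0.969 to 0.976. The lowest was between p57-/- replicate 1 and p57+/+ replicate 2. The ratio of 3' to 5' signal was 0.945 to 1.18 for Gapdh and 1.56 to 1.76 for Actb.

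The samples held transcripts of the surface layers and of other liver cells. In the mesothelium list the brightest probe sets over all 4 arrays were of Krt8 and Krt18, keratin genes that hepatocytes and bile duct cells also express, and of the adhesion molecule gene Alcam, at 4830 ± 902, 4263 ± 479 and 2641 ± 17.9 (SD, n = 2) in p57+/+. The uroplakin gene Upk3b, named after its value was seen, had a mean of 3061 in p57+/+. The fibrillar collagen genes Col3a1 and Col1a2 reached 26752 ± 3297 and 20792 ± 1530. Apoa1, Ttr and Afp, which encode plasma proteins made by fetal hepatocytes, lay between 56812 and 74260 on all 4 arrays. The granulocyte genes S100a8 and S100a9 lay between 54374 and 61717. Among erythroid genes, the anion exchanger Slc4a1 was at 29359 ± 1664 and the transferrin receptor Tfrc at 24652 ± 709 in p57+/+.

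Cdkn1c, which encodes the cyclin-dependent kinase inhibitor p57, was the only gene past the threshold in the main fit, which had no block. Its single tested probe set gave 10255 and 9866 in p57+/+ and 7.79 and 7.28 in p57-/-, where it was called Absent on both arrays. Its signal was at least 760-fold lower in p57-/-, and it fell past the threshold (limma adjusted p = 1.80e-08). The fitted log2 change of -10.38 (SE 0.20) rests on p57-/- signals under the lowest Present signal of each array, so only the bound measures its size. The labelled genotype and the Cdkn1c signal matched on all 4 arrays. No other probe set passed in either direction in the main fit, with 0 higher and 1 lower in limma. An alternative fit with the experiment number as a block called 10 higher and 20 lower, Cdkn1c included. At an unadjusted p under 0.05 the main fit gave 895 higher and 854 lower. The next lowest adjusted p was 0.143, for Acacb. Without p57-/- replicate 2, limma called 98 probe sets higher and 123 lower, and without p57-/- replicate 1 it called 1 and 11.

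Among probe sets at least 2-fold changed in both experiments, 38 were higher and 64 lower in p57-/-, 102 in all, beside 70 that changed in opposite ways. Most were dim. Of the 102, 86 had a geometric mean signal under 100, as did 59 of the 70. At a geometric mean signal of at least 500, which 10633 tested probe sets reached, 2 changed the same way and 1 changed in opposite ways. Across probe sets, which are not independent replicates, the log2 changes of the 2 experiments had a Pearson correlation of 0.112. Without Cdkn1c it was 0.0952, and 0.206 among probe sets with a geometric mean signal of at least 500.

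**Figure D1:**
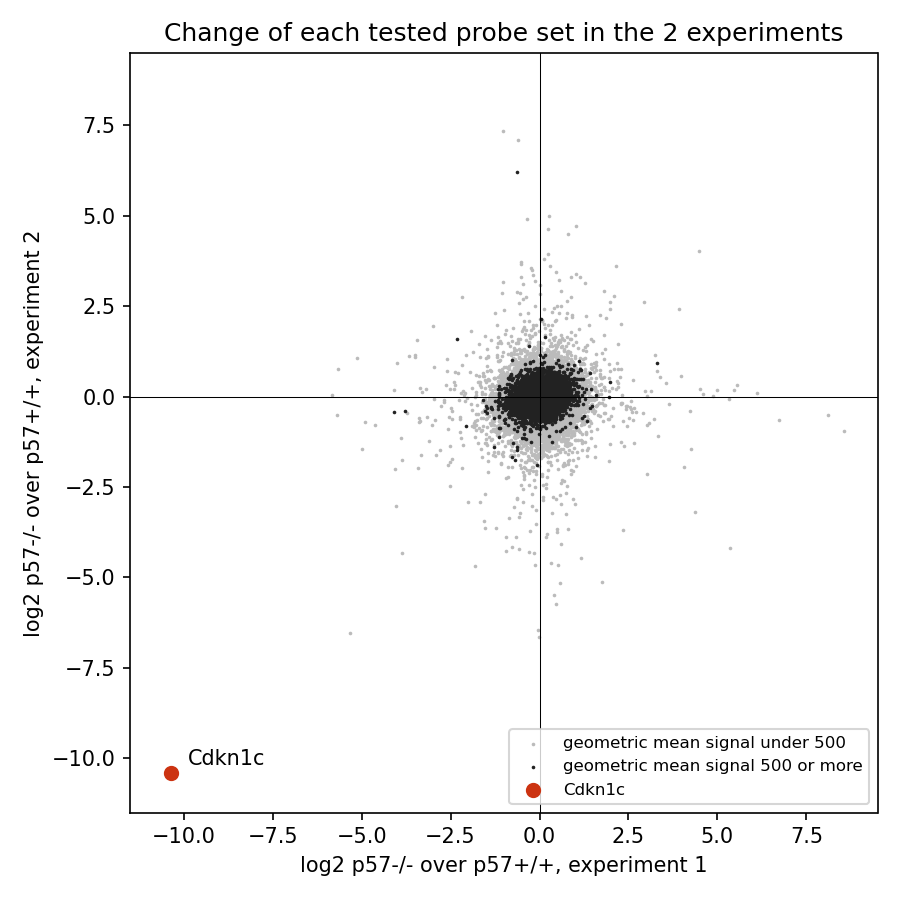
Log2 change of each of the 22800 tested probe sets in experiment 1 (horizontal) and experiment 2 (vertical), with dim probe sets in grey, those with a geometric mean signal of 500 or more in black and Cdkn1c in red. Cdkn1c lies at -10.36 and -10.40, and most other probe sets form a cloud around 0. Sex-linked probe sets lie far from 0 in 1 experiment. Eif2s3y went from 2.56 to 966 in experiment 1, and an Xist probe set from 4.84 to 783 in experiment 2.

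Of the genes higher in both experiments, none passed the test. The 12 of largest change were Col6a5, 2510009E07Rik, Zic1, Klrb1f, Sirpb1a, Atp6v1b2, Tmem38b, Glis3, Sox15, Cep89, Rrad and Tmem229b, all called Absent on both p57+/+ arrays. The steadiest was Zic1, a zinc finger transcription factor gene, at 17.5 and 19.5 in p57+/+ and 134 and 120 in p57-/-, at least 6.86-fold higher (adjusted p = 0.453). Bounds for the other 11 ran from at least 2.16-fold for Col6a5 to at least 4.30-fold for Sirpb1a. The probe sets of Tmem38b and Tmem229b disagreed in direction.

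Of the genes lower in both experiments, the largest changes after Cdkn1c were in 11 that did not pass. Among these 11, Acacb and Thrsp, both of fatty acid metabolism, had the smallest p-values. Acacb, which encodes the mitochondrial acetyl-CoA carboxylase that restrains fatty acid oxidation, gave 301 and 401 in p57+/+ and 74.0 and 53.4 in p57-/-, at least 5.52-fold lower. Thrsp, a gene that responds to thyroid hormone and carbohydrate, gave 132 ± 22.6 against 2.23 ± 0.902 (SD, n = 2), at least 9.90-fold lower (adjusted p = 0.453), while its other probe set was at -0.77 (SE 0.38). Dct, a melanin synthesis gene, and Alpi, an intestinal phosphatase gene, had bounds of at least 4.47-fold and at least 4.15-fold. Tinag and Plet1 were detected on 1 p57-/- array each. Tinag gave 123 and 189 in p57+/+ and 7.40 (Absent) and 47.2 in p57-/-, and Plet1 gave 125 and 193 against 42.8 and 17.7 (Absent). The others were Xpo7, Gm19500, Ptbp2, Psma5 and Hyal4. The probe sets of Xpo7, Ptbp2 and Psma5 disagreed in direction.

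Genes of DNA replication lay lower in p57-/- as a group. Of 23 tested genes of G1/S and DNA replication, 15 were lower in both experiments and 0 higher in both, with a median log2 change of -0.36 (camera adjusted p = 4.35e-10 at the preset correlation, and adjusted p = 0.712 with an estimated correlation). No member passed over all probe sets, and 3 did when adjusted over the list alone. These were genes of the replicative helicase, Mcm2 at -0.68 (SE 0.17), Mcm4 at -0.55 (SE 0.13) and Mcm6 at -0.58 (SE 0.15). The list's median change was -0.67 in experiment 1 and -0.07 in experiment 2, and -0.10 without p57-/- replicate 1 (adjusted p = 0.00936). Tyms had the largest change, -0.69 (SE 0.46). The 22 tested genes of G2/M and mitosis had a median of -0.09 (camera adjusted p = 0.115). That median was 0.14 without p57-/- replicate 1 (adjusted p = 0.0290) and -0.30 without p57-/- replicate 2 (adjusted p = 8.06e-07). Foxm1 was at -0.56 (SE 0.25) and Cenpe at -0.27 (SE 0.17).

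Ccnd1 and Ccnd2 encode D-type cyclins, partners of the kinases that p57 inhibits, and neither passed over all probe sets. Ccnd2 was at 2239 ± 264 in p57+/+ and 1099 ± 319 in p57-/- (SD, n = 2), with a log2 change of -1.05 (SE 0.20, adjusted p = 0.519). All 6 tested Ccnd2 probe sets were lower. Ccnd1 was at 2192 ± 55.2 and 1233 ± 312, with a log2 change of -0.85 (SE 0.18, adjusted p = 0.519), and 2 of its 3 probe sets were lower. The third D-type cyclin gene, Ccnd3, was at -0.16 (SE 0.16) and -0.01 (SE 0.27) with its 2 probe sets. Cdkn1b, which encodes the related inhibitor p27, was at 0.40 (SE 0.13). Ccnd3 and Cdkn1b were named after their values were seen. The list of CDK inhibitors and G1 regulators, with 15 tested genes, had a median of -0.18 and a mean of -0.89 (camera adjusted p = 8.98e-05, and adjusted p = 0.712 with an estimated correlation). Without Cdkn1c the other 14 had a median of -0.17 and a mean of -0.21 (adjusted p = 0.00899), a test added after the data were seen. The list's median was -0.46 in experiment 1 and -0.03 in experiment 2. Cdkn1c, Ccnd1 and Ccnd2 passed when adjusted over the list alone.

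Erythroid genes lay lower in p57-/- as a group. All 13 tested genes had lower means, 12 of them in both experiments, and the median log2 change was -0.45 (camera adjusted p = 6.67e-08, and adjusted p = 0.712 with an estimated correlation). Klf1, a master regulator of red cell genes, was at -0.60 (SE 0.18), and the blood group gene Rhd at -0.59 (SE 0.18). These passed when adjusted over the list alone, as did Tfrc, Ermap and Trim10. None passed over all probe sets. The median was -0.69 in experiment 1 and -0.26 in experiment 2, and -0.17 without p57-/- replicate 1 (adjusted p = 0.0146).

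Granulocyte and megakaryocyte genes had a median of 0.15 over 16 genes (camera adjusted p = 0.00424, and adjusted p = 0.712 with an estimated correlation). The protease gene Prtn3 was at 0.41 (SE 0.11) and the platelet factor gene Pf4 at 0.38 (SE 0.20). The median was 0.29 in experiment 1 and 0.03 in experiment 2, and the call was lost without p57-/- replicate 1 (adjusted p = 0.277). Macrophage genes had a median of 0.06 over 16 genes (camera adjusted p = 0.520), with Cd5l at -0.50 (SE 0.14) and Fcgr3 at 0.47 (SE 0.24). Without p57-/- replicate 2 the macrophage median was 0.26 (adjusted p = 0.0185).

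Genes of the mesothelium gave no call as a group, with a median of -0.02 and a mean of 0.04 over 20 genes (camera adjusted p = 0.520). Wt1, a transcription factor of mesothelial cells, was at 260 ± 7.83 in p57+/+ and 408 ± 63.9 in p57-/- (SD, n = 2), a log2 change of 0.64 (SE 0.21). Bnc1 was at 0.60 (SE 0.18) and Alcam at 0.39 (SE 0.12), while Krt8 was at -0.32 (SE 0.18) and Krt18 at -0.24 (SE 0.13). None of these passed. The median turned to 0.20 without p57-/- replicate 1 (adjusted p = 0.0290) and to 0.27 without p57+/+ replicate 2 (adjusted p = 0.00903).

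Lists of mesenchymal, stellate cell and TGF-beta target genes lay higher in p57-/-, mostly in experiment 1. The samples mix cell types, so these genes are not assigned to the layer beneath the mesothelium. The list of submesothelial fibroblasts and mesenchyme had a median of 0.27 over 20 genes, with 13 higher in both experiments and 2 lower (camera adjusted p = 8.49e-04, and adjusted p = 0.712 with an estimated correlation). Dcn, which encodes the matrix proteoglycan decorin, was at 8420 ± 722 in p57+/+ and 12276 ± 2819 in p57-/-, a log2 change of 0.53 (SE 0.16). Hepatic stellate cell genes had a median of 0.21 over 12 genes (camera adjusted p = 0.00755, and adjusted p = 0.717 with an estimated correlation). Among them Hhip, which encodes a Hedgehog-binding protein, was at 454 ± 23.1 and 811 ± 37.3, a log2 change of 0.84 (SE 0.16), higher with all 4 of its probe sets and past the threshold over the list alone. Rgs5 was at -0.92 (SE 0.42). The TGF-beta and BMP target list had a median of 0.16 over 15 genes (camera adjusted p = 0.00525, and adjusted p = 0.717 with an estimated correlation), with Ltbp2 at 0.88 (SE 0.53) and Smad7 at 0.69 (SE 0.32). The medians in experiments 1 and 2 were 0.34 and 0.06 for mesenchyme, 0.32 and 0.08 for stellate cells and 0.41 and 0.03 for TGF-beta. Without p57-/- replicate 1 the stellate and TGF-beta calls were lost (adjusted p = 0.447 and 0.500). The stellate call was also lost without the variance trend (adjusted p = 0.0510) and with the mean of all probe sets per gene (adjusted p = 0.0670).

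Genes of hypoxia and glycolysis lay higher in p57-/-, with 14 of 17 higher in both experiments, a median of 0.35 and camera adjusted p = 3.76e-06 (adjusted p = 0.712 with an estimated correlation). The glycolytic enzyme genes Aldoa, Tpi1 and Pgk1 were at 0.57 (SE 0.14), 0.36 (SE 0.11) and 0.33 (SE 0.11). Bnip3, a mitophagy gene, was at 0.46 (SE 0.10). These 4 passed when adjusted over the list alone, and none over all probe sets. Ankrd37 and Pfkp had the largest changes, 1.02 (SE 0.69) and 1.02 (SE 0.36). Pfkp was at 1.85 in experiment 1 and 0.19 in experiment 2. The list's median was 0.40 in experiment 1 and 0.30 in experiment 2.

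The calls at the preset correlation did not separate the genotypes from other groupings of the 4 arrays. The comparison of genotypes gave 8 lists past the threshold, 5 higher and 3 lower. The comparison of experiment 2 with experiment 1 gave 8, and the remaining way to split the arrays into pairs gave 10. With an estimated correlation each of these gave 0. Lists with an estimated correlation near 0, such as hypoxia and glycolysis (0.0546), were lost too. Those counts of 0 therefore do not tell correlated genes from too few arrays. For the genotypes, directional fry gave 0 (lowest adjusted p = 0.0518). Mixed fry passed the CDK and G1 list, which holds Cdkn1c (adjusted p = 4.32e-04), Hedgehog and Notch targets (0.00512) and Wnt targets (0.0473). The 2 splits other than genotype gave 0 probe sets past the threshold in limma, with 655 and 693 at an unadjusted p under 0.05, beside 1749 for the genotypes. Any genotype difference adds to the spread within the groups of these 2 splits, so their counts are not a level without effect. Without p57-/- replicate 2 some named genes passed with log2 changes over 1.5 times as large, Pfkp at 1.69, Pdgfc at 1.73, Rhd at -0.90, Apoc3 at 1.14, Fcgr3 at 0.89, Pf4 at 0.74 and Cxcl1 at 1.29.

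**Figure D2:**
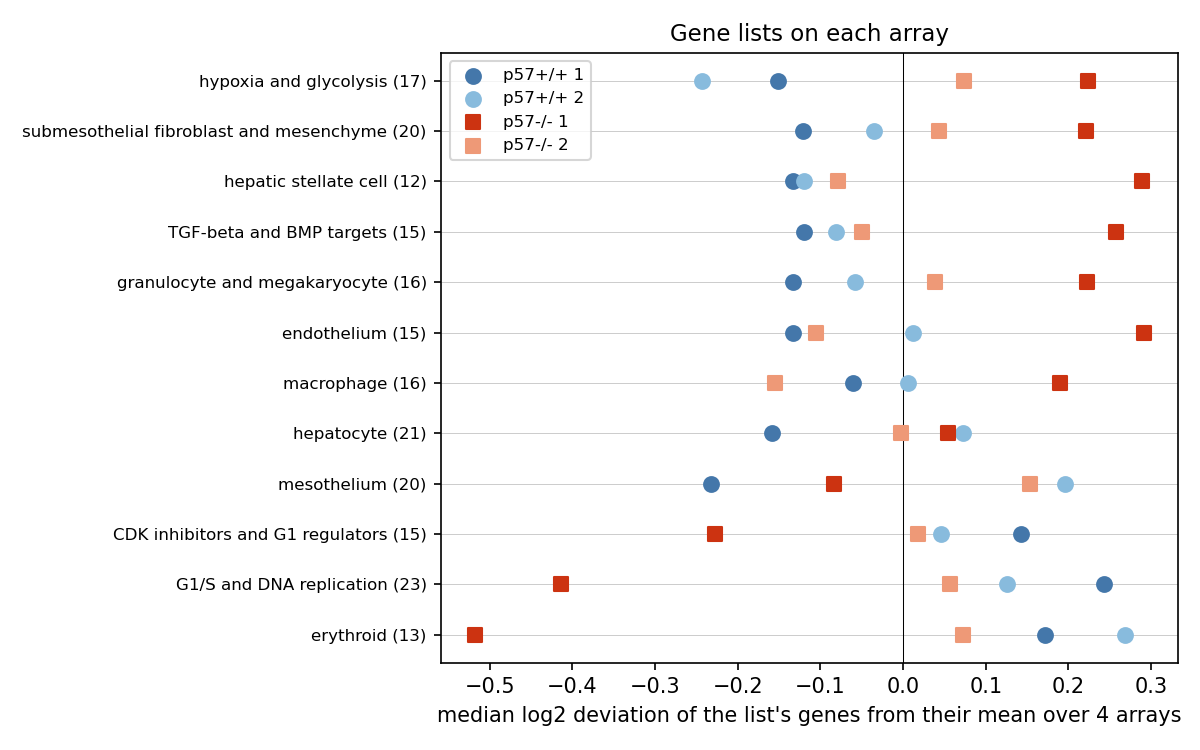
Median log2 deviation of each list's tested genes from their mean over the 4 arrays, per array, with the number of genes in parentheses, circles for p57+/+ and squares for p57-/-. The 8 lists past the camera threshold and the mesothelium, hepatocyte, macrophage and endothelium lists are shown, and p57-/- replicate 1 stands farthest from 0 for the erythroid list, at -0.52.

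The lists of other cell types did not pass with all 4 arrays. Hepatocyte genes had a median of 0.04 over 21 genes (camera adjusted p = 0.435), of 0.20 in experiment 1 and -0.15 in experiment 2, with Cyp2e1 at -0.55 (SE 0.21) and Apoc3 at 0.32 (SE 0.41). Of these genes 18 had a geometric mean signal over 20000, on arrays whose highest signals were 61858 to 74260, which limits what the list can show. The dimmest Afp probe set was at -1.15 (SE 0.39), and the other 3 lay between -0.02 and 0.07. The hepatocyte median was -0.00124 after quantile normalization and 0.17 without p57+/+ replicate 2 (adjusted p = 8.50e-05). Endothelial genes had a median of 0.11 over 15 genes (adjusted p = 0.255), with Cdh5 at 0.44 (SE 0.21) and Robo4 at 0.30 (SE 0.25). That list passed without p57+/+ replicate 2 (median 0.20, adjusted p = 0.0356) and without p57-/- replicate 2 (median 0.35, adjusted p = 0.00375). Smooth muscle and myofibroblast genes had a median of 0.07 over 7 genes (adjusted p = 0.509), with Tpm2 at 0.32 (SE 0.16) and Acta2 at -0.29 (SE 0.17). Too few genes of the bile duct (3), skeletal muscle (2) and pancreas, gut and adrenal (4) lists were detected for a test. In the last of these, Fabp2 at -0.77 (SE 0.22) and Vil1 passed over the list alone, in opposite directions. Vil1 gave 18.0 and 54.0, both Absent, in p57+/+ and 81.5 and 104 in p57-/-. The skeletal muscle gene Mylpf gave 1222 in p57+/+ replicate 1 and 218 to 299 on the other arrays.

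Imprinted genes other than Cdkn1c had a median of 0.09 over 23 genes (camera adjusted p = 0.346). Igf2 was at 0.02 (SE 0.13), and Zdbf2 was at 0.62 (SE 0.27). In the gene order of the reference, Slc22a18 and Phlda2 are the first tested genes on one side of Cdkn1c. Phlda2 was at 1247 ± 23.6 in p57+/+ and 873 ± 92.4 in p57-/-, a log2 change of -0.52 (SE 0.15). One Slc22a18 probe set was at -1.02 (SE 0.25) and the other at 0.03 (SE 0.22). On the other side, Kcnq1ot1 was at 0.08 (SE 0.20). Igf2 and Kcnq1ot1 were named after their values were seen. The list of 17 tested neighbours had a median of -0.04 (camera adjusted p = 0.255), and Slc22a18 passed over the list alone.

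The other signalling and matrix lists did not pass in the main test, and 3 of them passed in some alternatives. Wnt targets had a median of 0.15 over 15 genes (camera adjusted p = 0.163), with the secreted inhibitor Wif1 at 1.48 (SE 0.34), from 68.1 ± 6.01 to 195 ± 67.0. Wif1, Sfrp2 and Ccnd1 passed over the list alone. The Wnt list passed with the mean of all probe sets per gene (adjusted p = 0.0449). Hedgehog and Notch targets had a median of 0.06 over 14 genes (adjusted p = 0.394), with Hes5 at -0.92 (SE 0.51). Secreted growth factors had a median of 0.14 over 25 genes (adjusted p = 0.235), with Pdgfc at 1.14 (SE 0.34), from 1.77 in experiment 1 and 0.51 in experiment 2, and Fgf7 at -0.71 (SE 0.63), and passed without p57-/- replicate 2 (adjusted p = 0.00914). Haematopoietic niche factors had a median of 0.17 over 8 genes (adjusted p = 0.255), with Csf1 at 0.47 (SE 0.20) and Angpt1 at 0.38 (SE 0.37). Basement membrane and matrix remodelling genes had a median of 0.28 over 21 genes (adjusted p = 0.0655), with the laminin gene Lama2 at -0.86 (SE 0.22). This list passed in 6 of 18 settings (lowest adjusted p = 0.00650). Lama5, another laminin gene, was Absent on both p57+/+ arrays and at least 1.71-fold higher in p57-/-. Genes of epithelial-mesenchymal transition had a median of 0.16 over 14 genes (adjusted p = 0.151), with Krt14 at 0.75 (SE 0.47) and Zeb2 at 0.37 (SE 0.20).

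Retinoic acid pathway genes had a median of 0.10 and a mean of -0.04 over 7 genes (camera adjusted p = 0.744), with Aldh1a1 at -0.65 (SE 0.34) and Aldh1a2 at -0.38 (SE 0.35). Targets of p53 had a median of 0.10 and a mean of 0.0057 over 13 genes, with camera's direction lower (adjusted p = 0.964), Bcl2 at -0.51 (SE 0.26) and Aen at -0.35 (SE 0.24). Interferon response genes had a median of -0.08 over 14 genes (adjusted p = 0.521), with Ifit1 at 0.54 (SE 0.44) and Rsad2 at -0.33 (SE 0.27). Immediate early and stress genes had a median of 0.08 over 19 genes (adjusted p = 0.239), and of 0.25 without p57-/- replicate 2 (adjusted p = 0.0122). Gadd45b, a stress-response gene, was at 458 ± 37.3 in p57+/+ and 947 ± 126 in p57-/-, a log2 change of 1.04 (SE 0.17, adjusted p = 0.453), and it passed over the list alone with Klf6. Atf3 was at 0.77 (SE 0.27). Chemokine and inflammation genes had a median of 0.21 over 7 genes (adjusted p = 0.744), with Il6 at 0.95 (SE 0.64) and Cxcl1 at 0.73 (SE 0.34), and Saa3 passed over the list alone.

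The sex-linked genes differed between the p57+/+ arrays. Xist, the RNA of the inactive X chromosome, gave 12199 in p57+/+ replicate 1 and 86.7 in p57+/+ replicate 2 with its brightest probe set, called Present on both. The other 2 Xist probe sets were Absent in replicate 2, at 6.29 and 4.84. The Y-linked gene Eif2s3y gave 2.56, called Absent, in replicate 1 and 1734 in replicate 2. Both p57-/- arrays carried both transcripts, with Xist at 7889 and 6412 and Eif2s3y at 966 and 904.

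**Figure D3:**
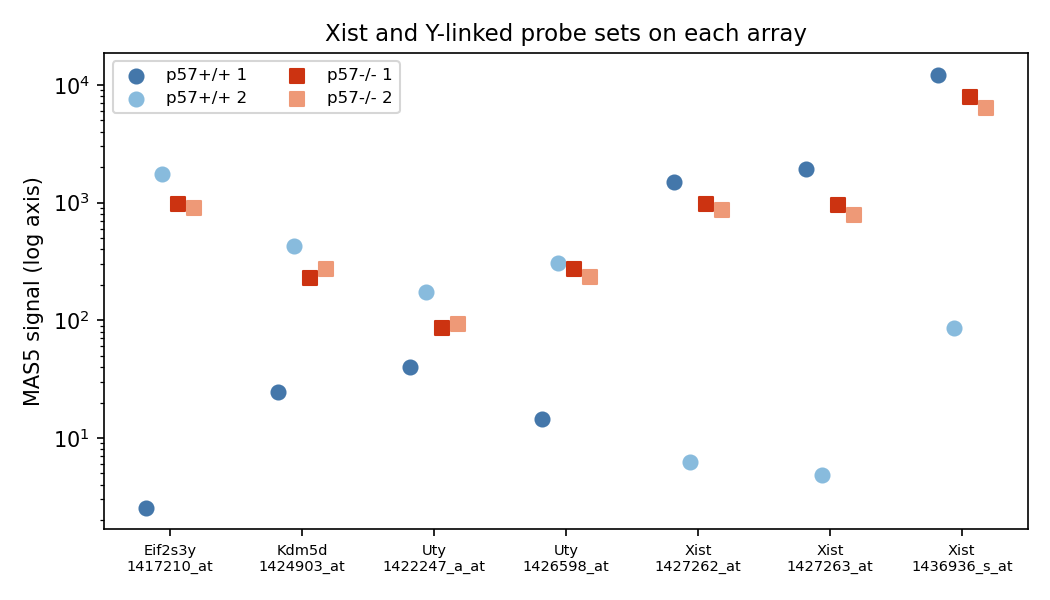
MAS5 signal, on a log axis, of each Xist and Y-linked probe set on the 4 arrays, with circles for p57+/+ and squares for p57-/-. Each p57-/- array shows both kinds of transcript, and each p57+/+ array shows mainly 1 kind, with 1 Xist probe set at 86.7 in p57+/+ replicate 2.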

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

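All alternatives but 1 were chosen before the data were examined. The list of CDK inhibitors without Cdkn1c was added after seeing the data, and 8 lists passed with it. Cdkn1c kept its direction and its call in all 14 settings that tested it, with log2 changes from -10.43 to -7.14. The filter to probe sets Present on all 4 arrays removes it by construction, so 0 probe sets were lower there. The 102 probe sets changed at least 2-fold the same way became 47 with a pseudocount of 16, 10 with 64, 14 with the filter to Present on all 4 arrays, 2868 with no filter, 555 at 1.5-fold and 30 at 3-fold. The cause was not tested, apart from the filters and folds, which set how many probe sets can count.

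Whether the experiment numbers pair the samples was left open. The titles give each number to 1 sample of each genotype, but the labels do not say what an experiment shared. Across probe sets, the difference of experiment 2 from experiment 1 in p57+/+ and that in p57-/- had a correlation of 0.0046. Some genes still followed the number. Hbb-y, picked after its values were seen, gave 3116 and 3082 in experiment 1 with 1 of its probe sets. That probe set gave 1233 and 1277 in experiment 2. Its other probe sets followed the number too, as at 1183 and 1016 against 396 and 390. Hspa1b, also picked afterwards, gave 585 and 969 in experiment 1 and 231 and 272 in experiment 2 with its brightest probe set. How many genes follow the number was not counted. With the replicate block, 10 probe sets were higher and 20 lower. The block with quantile normalization gave 22 and 33. The called genes then included Scd1, Acacb, Thrsp, Ccnd1, Ccnd2, C9, Mbl2, Gadd45b and Igfbp2. Of the 107 named genes other than Cdkn1c, 6 passed under the block, and 20 passed under at least 1 setting without the block.

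Leaving out 1 array leaves a lone sample that is assumed to vary like the other genotype. The count of higher probe sets then ran from 1 to 98 and of lower ones from 1 to 123. It was 98 and 123 without p57-/- replicate 2, 1 and 11 without p57-/- replicate 1, 6 and 3 without p57+/+ replicate 2, and 4 higher without p57+/+ replicate 1. The arrays' sexes account for part of this. Without p57+/+ replicate 1, 3 of the 4 higher probe sets were of Xist, and without p57+/+ replicate 2 the higher ones included the Y-linked Eif2s3y, Kdm5d and Uty. The number of lists ran from 7 to 14, with 14 without p57-/- replicate 2. It was 0 with an estimated correlation and 0 with directional fry. Under the other settings it ran from 7 to 10. The cause of the other changes was not tested.

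Changes of direction were all in values that had not passed in the main fit. Not all were small, as the G2/M and mesothelium medians with 1 array left out show. With quantile normalization, with or without the block, S100a8 was at -0.0127 and the hepatocyte list at -0.00124. With no filter, the neighbours of Cdkn1c were at 0.0088, the retinoic acid list at -0.0582 and p53 targets at -0.0284. Over the arrays left out, the log2 change ran from -0.16 to 0.12 for Afp, -0.99 to 0.24 for Aldh1a2, -0.10 to 2.15 for Ankrd37, -0.0274 to 0.17 for Apoa1, -0.49 to 1.14 for Apoc3 and -0.0347 to 0.37 for Colec11. It ran from -0.19 to 0.29 for Csf1r, -0.20 to 0.0024 for Hsd3b1, -0.25 to 0.0735 for Lyve1, -0.0185 to 0.10 for Mylk, -0.15 to 0.51 for Onecut1 and -0.16 to 1.16 for Prrx1. For Rsad2 it was -0.76 to 0.0882, for Slc40a1 -0.0116 to 0.16 and for Ttr -0.20 to 0.19. List medians ran from -0.30 to 0.14 for G2/M, -0.0124 to 0.0867 for Hedgehog and Notch, -0.0718 to 0.35 for endothelium, -0.0610 to 0.17 for hepatocytes and -0.0601 to 0.25 for immediate early genes. They ran from -0.22 to 0.0543 for interferon, -0.0777 to 0.26 for macrophages, -0.21 to 0.27 for mesothelium and -0.0365 to 0.0418 for p53 targets.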

Other observations

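The lists of lipid and liver metabolism used here were written after the smallest p-values had been seen, without the genes seen there. The tests of fewer hepatocytes, of the level of p57-/- replicate 2, of erythroid cells and of the sex-linked signals were chosen after the result was seen. The tests of lipid synthesis and hepatocyte maturation were set before their results were seen, but the gap between experiments was added to the reading of the maturation test afterwards.

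Several genes of liver metabolism, singled out after their values were seen, had small p-values though none passed. C9 and Mbl2, which encode complement proteins made by hepatocytes, had log2 changes of -2.16 (SE 0.28) and -1.35 (SE 0.23). The fatty acid desaturase genes Scd1 and Fads2 were at -1.44 (SE 0.34) and -0.85 (SE 0.18) with their brightest probe sets. Scd1 was at -2.14 without p57-/- replicate 2, and its other probe set was at -0.67 (SE 0.23). In the other direction, Ppara, a regulator of fatty acid oxidation, was at 0.77 (SE 0.15), Pdk4, which limits glucose oxidation, at 0.93 (SE 0.22), and the IGF-binding protein gene Igfbp1 at 0.63 (SE 0.14). Igfbp2 gave 890 and 1285 in p57+/+ and 8788 and 2431 in p57-/-. A list of fasting and fatty acid oxidation genes had a median of 0.35 over 13 genes, with 10 higher in both experiments and 0 lower in both (camera adjusted p = 8.83e-06, and adjusted p = 0.192 with an estimated correlation). Cpt1a and Angptl4 were each at 0.68, with 1.09 and 0.88 in experiment 1 and 0.28 and 0.49 in experiment 2. Cholesterol synthesis genes had a median of -0.18 over 14 genes, with 11 lower in both experiments (camera adjusted p = 2.21e-04, and adjusted p = 0.349 with an estimated correlation).

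The first pattern is the lower signal of 7 liver genes, Acacb, C9, Ces1d, Thrsp, Ugt2b36, Mbl2 and C4bp, with a median log2 change of -1.30. Fewer hepatocytes would lower other liver genes alike, but of the 31 genes of the maturation list, the 29 with a signal under 20000 had a median of -0.0021, with quartiles at -0.27 and 0.24. For a delay in hepatocyte maturation, the same 31 genes were at -0.0021. Their 0.08 in experiment 1 lay above the bound of -0.1, so the prediction set beforehand failed. Experiment 2 gave -0.17, a gap of 0.25, with 10 genes higher in both experiments and 9 lower in both. Given that gap, weighed only afterwards, a delay is not excluded. For lower lipid synthesis, 20 genes other than those of the smallest p-values had a median of -0.29, with -0.27 and -0.24 in the 2 experiments. Of them 17 were lower in both, and the other splits gave medians of 0.20 and -0.03. A member, Fasn, was at -0.99 in the alternative without p57-/- replicate 2, so not all 20 may have been unseen. Of 10000 random lists of matched signal 0% were lower, but random lists ignore the correlation between genes. With an estimated correlation the camera adjusted p was 0.349, in a form of the test with few degrees of freedom on so few arrays. These genes were measured on the same arrays and may vary together with the genes seen, so they are not an independent test. A shift in the feeding or metabolic state of the p57-/- embryos or their mothers may underlie the lower lipid synthesis list. A direct part of p57 was not tested. The list's array medians for p57+/+ replicate 1 (0.05) and p57-/- replicate 2 (-0.01) lie close together.

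The second pattern is the lower signal of erythroid and DNA replication genes, with p57-/- replicate 1 farthest from the other arrays. Without that array, p57-/- replicate 2 lay lower than the p57+/+ mean, by -0.17 for erythroid and -0.10 for DNA replication genes. In experiment 2, 12 of 13 erythroid and 15 of 23 DNA replication genes were lower. The genes of each list vary together, with estimated correlations of 0.887 and 0.710, so these counts are not separate observations. Both values exceed the median differences between the p57+/+ arrays, 0.12 and 0.0070, but in such medians rises and falls cancel. The array medians of the DNA replication list were 0.24 and 0.13 in p57+/+ and 0.06 in p57-/- replicate 2, so the 0.0070 understates the spread. The values are smaller than the -0.45 and -0.36 over all 4 arrays and rest on 1 p57-/- array. How much of either part p57-/- replicate 1 carries stays open. Fewer erythroid cells in the p57-/- samples may account for the erythroid part but were not put to a test that could decide, since the SD of the 13 changes, 0.92 times their median standard error, is small for any cause at an estimated correlation of 0.887. The other splits of the arrays gave at least as many list calls.

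The third pattern is the presence of Xist and Y-linked signal together on both p57-/- arrays. Arrays exchanged between genotypes would leave Cdkn1c signal on a p57-/- array, and the highest there was 7.79. Xist as a share of p57+/+ replicate 1 and Y-linked signal as a share of p57+/+ replicate 2 added to 1.19 and 1.12 on the p57-/- arrays, near the 1 that a mixture of both sexes gives, so each p57-/- sample may have been pooled from embryos of both sexes. The p57+/+ arrays differed, with Xist but Y-linked Eif2s3y Absent in replicate 1, and Y-linked signal with Xist at 86.7 in replicate 2. No biological explanation was tested for this pattern.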
